A study of Mus musculus with 5 samples.

How the data were processed

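Gene expression was measured by microarray in 5 samples from untreated C57/B6 mice heterozygous for a GFP reporter knocked into the stem cell factor locus (Scf, the gene Kitl). Per the labels' protocols, 5000 cells were sorted into Trizol for each sample, total RNA was extracted and amplified with the Ovation Pico WTA System V2, and the resulting cDNA was fragmented and biotin-labelled with the Encore Biotin Module. There were 2 groups: whole spleen cells (2 arrays) and VE-cadherin-negative Scf-GFP-positive cells that had been sorted (3 arrays). Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which can be partly technical.

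The deposited values are log2 levels per probe set. They were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; the versions of both, the array design and any further filter are not given in the sources used here. RMA corrects the background of each array, quantile-normalizes the arrays and summarises the probes of a probe set on a log2 scale, so none of these steps was repeated for the main result. Whether the 5 arrays went through RMA in 1 run is not given in the sources used here. The values ran from 1.43 to 13.3, with medians between 5.01 and 5.12 on the 5 arrays. The interquartile range differed between arrays, from 2.11 to 3.04, which leaves open whether they were normalized together. Quantile normalization applied again, an alternative, evens out the distributions but not differences in how separate runs summarise the probes. A second deposited table, the series matrix, held the same log2 values (largest difference 0), so exchanging the tables moved nothing. All sample columns of both tables were used. Arrays give no read depth, and their number, 3 against 2, limits the precision.

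The authors' table pairs probe sets with gene symbols. Of 28940 probe sets, 24418 had 1 symbol, 43 had several and 4479 had none. Where a gene had several probe sets (1810 of the 21310 genes), the probe set with the highest mean over all 5 arrays stood for it. Probe sets with no symbol or several were kept out of the gene analysis. Transcript accessions of 21024 of the probe sets with 1 symbol were found in a RefSeq table of assembly GRCm38.p6, which was used for names only, and 1927 of them had a newer symbol; the symbols printed are those of the deposited table. The table's descriptions cite transcripts of the older build NCBIM37, so no coordinates are given.

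Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings) as sorted cells minus whole spleen, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and counts were also made with a minimum change of 2-fold (1 on the log2 scale). Standard errors are limma's moderated ones. The fit had 3 residual degrees of freedom and limma added a prior worth 3.26. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots. No filter on dim probe sets and no block were used. Gene lists were tested with camera from limma at its preset inter-gene correlation of 0.01, adjusted over the 27 lists with at least 5 measured genes. Counts of members past the threshold are given after adjustment over all genes and, as a second count, adjusted over the list alone. Correlations between arrays were computed across probe sets, which are not independent replicates.

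The tests, the groups, the 28 gene lists and the rule for naming genes were fixed before the data were examined. The rule took the sort genes Kitl and Cdh5; the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out predicted genes and antigen receptor segments; the 4 called members of each list with the largest change in the list's main direction, and called members going the other way where they were 5 or fewer. Members that did not pass are named as exceptions, and any member of the niche factor, perivascular and spleen patterning lists could be named; a result that this rule allowed is not reported here. The lists, written from textbook knowledge, were sort genes, niche factors, perivascular mesenchymal stroma, spleen mesenchyme patterning factors, fibroblastic reticular white pulp stroma, mural and smooth muscle contractile genes, extracellular matrix, complement and coagulation inhibitors, BMP and TGF-beta signalling, Wnt and Notch signalling, osteogenic, adipogenic and chondrogenic genes, endothelial, mesothelial, Schwann and glial, B cell, T and NK cell, macrophage and monocyte, dendritic cell, neutrophil and mast cell, erythroid, and megakaryocyte and platelet markers, haematopoietic stem and progenitor genes, proliferation, immediate early and stress genes, the interferon response, and adhesion molecules and integrins of stroma.

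The alternatives were the series matrix values, quantile normalization applied again, median centring, removal of the dimmest 25% of genes, the mean of a gene's probe sets, trend and robust eBayes, array weights, replicate number as a block, leaving out each array in turn, limma's treat against a 2-fold change, and for lists an estimated correlation, fry and camera on ranks. List members and gene families were also counted without each array, and again after quantile normalization; these counts were chosen after seeing the data.

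The steps were tested on simulated data: 20 sets of 3 against 2 arrays with 21310 genes, 200 of them changed. The limma step called 1.3% of the genes changed by 1 log2 unit and 66.5% of those changed by 2 log2 units, and 6.68% of its calls were false. A list of 20 genes shifted by 1 log2 unit was called in 100% of the sets, and 0 of 540 unchanged lists were called. Changes of about 2-fold in single genes are therefore mostly missed by a comparison of this size, at least where as few genes change. The simulated genes varied independently, with the same SD in both groups. In the data the estimated correlation within lists reached 0.90 (mesothelial genes). The median SD was 0.35 in whole spleen and 0.21 in sorted cells. The simulation therefore cannot show how often lists are called falsely in these data.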

Results

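The series profiled VE-cadherin-negative Scf-GFP-positive cells, the non-endothelial cells that express stem cell factor, against unfractionated spleen cells of the same reporter strain. Stem cell factor is a ligand that haematopoietic stem cells depend on, and the title of the series concerns the spleen as a site of blood formation outside the marrow. VE-cadherin is an adhesion protein of endothelial cells, and the sort removed cells that carry it. Each of the 5 arrays, 3 of sorted cells and 2 of whole spleen, started from 5000 cells and gave a log2 RMA level for 28940 probe sets covering 21310 named genes. The labels conflict about the tissue of the sorted cells: the growth protocol places them in bone marrow, while the title speaks of the spleen and the comparison group is spleen. They are called sorted cells here.

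The 3 sorted arrays resembled one another more than the whole spleen arrays did. Pearson correlations across probe sets were 0.967 to 0.976 between sorted arrays and 0.887 between the 2 whole spleen arrays. Between the groups they were 0.784 to 0.795 for whole spleen array 1 and 0.867 to 0.868 for whole spleen array 2. Whole spleen array 2 was thus almost as close to the sorted arrays as to whole spleen array 1. The median SD per gene was 0.21 log2 units in sorted cells (n = 3) and 0.35 in whole spleen (n = 2). The first principal component held 67.7% of the variance and separated the groups. It also placed whole spleen array 1 (-138.4) far from whole spleen array 2 (-72.8), with the sorted arrays at 66.0 to 76.4. The second component, with 19.96%, separated the whole spleen arrays from each other. Whole spleen array 1 also had the narrowest distribution, with an interquartile range of 2.11 log2 units against 2.76 to 3.04 on the other 4 arrays. The median difference of all genes was -0.22 log2 units, and -0.08 after quantile normalization was applied again, so list medians are given relative to the median of all genes unless called uncorrected. Whether the 5 arrays were normalized together is not given in the sources used here.

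The comparison asks which genes set the Scf-expressing cells apart from the spleen as a whole. Among the gene lists, contractile genes of mural cells had the highest median, 4.75 log2 units above all genes, followed by complement genes (3.27) and niche factors (3.26), and B cell (-3.53) and T and NK cell markers (-2.49) had the lowest. The largest rises were those of Sparcl1, a matricellular protein (7.34 ± 0.28 log2 units, SE, probe set 10531931), Acta2, smooth muscle actin (7.16 ± 0.38), Serping1, the inhibitor of complement C1 (7.04 ± 0.24), and C1s, a protease of the C1 complex (7.02 ± 0.23). Sparcl1 stood at 12.12 ± 0.13 in sorted cells (SD, n = 3) and at 4.78 ± 0.46 in whole spleen (SD, n = 2) (adjusted p = 0.00053). The next largest rises were those of Aspn (6.61), Myl9 (6.57), Hmcn1 (6.41), Igfbp3 (6.30), Timp3 (6.18), Cxcl13 (6.11), Kazald1 (6.11) and Dcn (6.06). Aspn and Dcn encode small leucine-rich proteoglycans, Timp3 an inhibitor of matrix metalloproteinases, and Igfbp3 a binding protein of insulin-like growth factors. Hmcn1 was read by 27 probe sets, whose differences ran from 2.60 to 6.41. Outside antigen receptor segments and predicted genes, 5 of which ranked above the last gene named here, the largest falls were those of Ms4a1, the B cell antigen CD20 (-6.24 ± 0.28 log2 units, probe set 10466172), and of S100a9 (-5.98 ± 0.55) and S100a8 (-5.89 ± 0.68), the subunits of calprotectin in neutrophils. Cd79b (-5.45), Dapl1 (-5.37), Ly6d (-5.32), Fcer2a (-5.16), Il7r (-5.08), Gimap7 (-5.08), Bank1 (-4.999), Faim3 (-4.99) and Gmfg (-4.92) followed. Gmfg lost its call without whole spleen array 1 (adjusted p = 0.064) and with array weights (0.054), and its other probe set differed by -0.94. No background level was set, and in the group where they were lower these 24 genes stood at percentiles 7.63 (Aspn) to 61.8 (Cxcl13) of all genes. Differences measured against the dimmest of them, such as Aspn and C1s (percentile 8.19), are uncertain in size, and their order is not firm. All of the 24 except Gmfg kept their calls in all 13 settings tried. The series matrix is counted among these settings, though it holds the same values and could not differ.

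In all, 1890 of 21310 genes passed an adjusted p of 0.05 in limma, 1275 higher and 615 lower in sorted cells, and 1888 of them differed by at least 2-fold. In each of the 1890 the groups did not overlap, a separation seen in 49.3% of all genes where chance alone gives 20%. Immunoglobulin and T cell receptor segments made up 13 of the lower genes. The count rested on single arrays: it was 7115 without whole spleen array 2 (3137 higher, 3978 lower), 1231 without sorted array 1, 943 without sorted array 2 and 1078 without sorted array 3. In the first case the lone whole spleen array was assumed to vary as the sorted arrays do. The same assumption held without whole spleen array 1, where fewer genes passed than with all arrays. The assumption by itself therefore does not explain the large count. Among 177 called genes of the lists, 101 kept the call in all 13 settings. Array weights ended 67 of those calls, including every gene named below as losing its call without 1 array except Cd36, Ccna2 and Ccr7. Further quantile normalization ended the calls of Cd36, Cd74, Gpm6a, H2-Aa, H2-Ab1, Hlf, Mki67, Nkx2-3 and Top2a among the genes named below (adjusted p 0.0507 to 0.094). Median centring ended those of Egr3, Mki67 and Nusap1, trend and robust settings those of Egr3, Hlf, Nkx2-3 and Sox18, removal of dim genes that of Sox18, and the mean of probe sets that of Top2a (0.0505 to 0.143).

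Kitl, the gene that carries the reporter, was read by probe set 10366052. The cells were sorted on that reporter, so a rise of Kitl checks the sort and is no separate finding. Its levels were 8.19, 7.98 and 7.46 log2 units on the sorted arrays and 3.19 and 3.56 on the whole spleen arrays, a difference of 4.51 ± 0.30 (SE; adjusted p = 0.00093). Cdh5, which encodes VE-cadherin (probe set 10574438), stood at 4.45, 4.12 and 4.28 in sorted cells against 4.93 and 5.50 in whole spleen. The difference of Cdh5, -0.93 ± 0.27, did not pass over all genes (limma adjusted p = 0.097) or adjusted over the endothelial list alone. Adjusted over the 2 sort genes alone, the difference of Cdh5 had a p of 0.013. Without whole spleen array 1 it was -1.21 and just passed (adjusted p = 0.0497), while its adjusted p ran from 0.071 to 0.317 in the other alternatives. All 5 Cdh5 levels were near the middle of the array's range or below it, where RMA compresses differences.

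Factors that stromal cells supply to blood cells rose together in the sorted cells. Of 20 measured niche factors, 13 rose and 7 did not pass (14 rose when adjusted over the list alone), and the list's median lay 3.26 log2 units above that of all genes (camera adjusted p = 8.3e-14; adjusted p = 0.048 with an estimated correlation). The chemokines Cxcl13 (6.11 ± 0.26) and Cxcl12 (5.19 ± 0.38) led the list, followed by Csf1 (4.91 ± 0.33), the growth factor of macrophages, and by Kitl. Kitl, one of the 13, was set to rise by the sort on its reporter. Cxcl12, which retains stem cells in their niche, reached a mean of 11.84 in sorted cells. Il34, a second ligand of the Csf1 receptor (4.28 ± 0.25), the Notch ligand Jag1 (4.26 ± 0.54), Gas6 (4.25 ± 0.24), Angpt1, the ligand of the receptor Tek (3.62 ± 0.39), and Wnt5a (2.27 ± 0.29) also rose. Bmp4 (3.37), Vcam1 (3.14), Il7 (2.93) and Igf1 (2.25) rose less firmly. Bmp4 lost its call without whole spleen array 1, sorted array 2 or sorted array 3 (adjusted p 0.053 to 0.075), Vcam1 without whole spleen array 1 or any 1 sorted array (0.062 to 0.130). Il7 lost it without whole spleen array 1 or sorted array 3 (0.053 to 0.061), and Igf1 without sorted array 2 or 3 (0.070 to 0.071). Flt3l (1.48), Il15 (1.34), Pdgfa (0.73, and -0.28 at its other probe set), Il6 (0.67), Ptn (0.32), Thpo (-0.07) and Spp1 (-0.29) did not pass.

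**Figure D1:**
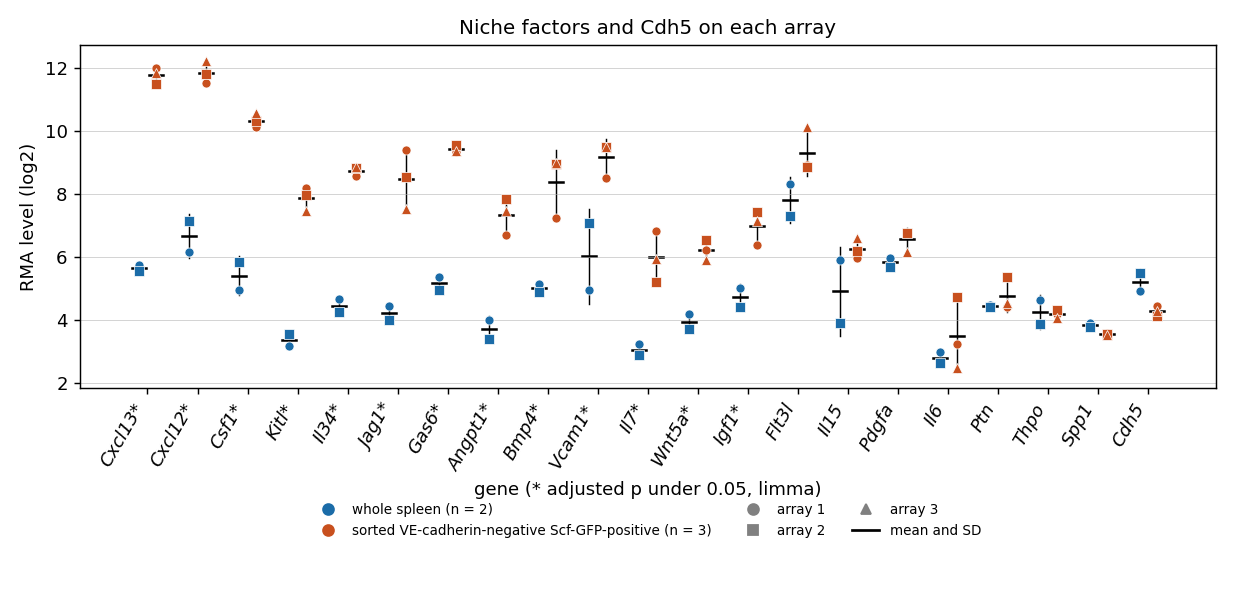
RMA levels (log2, vertical axis) of the 20 niche factors and of Cdh5 on each of the 5 arrays; points are arrays, horizontal bars group means and vertical bars SDs, with whole spleen (n = 2) in blue, sorted cells (n = 3) in orange and an asterisk on genes past an adjusted p of 0.05. For the 13 genes with an asterisk all 3 sorted arrays lie above both whole spleen arrays, while the 5 levels of Spp1 lie between 3.52 and 3.92.

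Genes of perivascular mesenchyme rose for 11 of 20 measured members (12 when adjusted over the list alone), with a list median 1.95 above that of all genes (camera adjusted p = 2.8e-08; adjusted p = 0.12 with an estimated correlation). The count was 7 without sorted array 2 and 7 without sorted array 3, and without whole spleen array 2 a member fell. The platelet-derived growth factor receptors Pdgfrb (4.69 ± 0.28) and Pdgfra (4.32 ± 0.59) rose, as did Lpl, lipoprotein lipase (4.11 ± 0.31), and the homeobox gene Prrx1 (3.79 ± 0.29). Lepr, the leptin receptor, rose by 3.36 ± 0.51 but not without whole spleen array 1 (adjusted p = 0.054). Thy1 (-1.37), Ebf3 (-0.20), Ly6a (-0.02), Twist1 (0.32) and Foxc1 (1.44) did not pass.

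Some of the transcription factors that pattern the splenic mesenchyme of the embryo were among the strongly raised genes. Of 14 measured members 6 rose and none fell (10 rose when adjusted over the list alone), with a median 1.72 above that of all genes (camera adjusted p = 3.1e-06; adjusted p = 0.12 with an estimated correlation). Nr2f2 (5.50 ± 0.27) and Tcf21 (5.25 ± 0.52) rose most, then Meis1 (3.68 ± 0.45), Wt1 (3.67 ± 0.51) and Tlx1 (3.04 ± 0.41), a factor without which the spleen does not form. Nkx2-3 rose by 1.23 ± 0.26, but not without whole spleen array 1 or any 1 sorted array (adjusted p 0.083 to 0.127) nor after further quantile normalization (0.051). Nkx2-5 (1.21), Nkx3-2 (1.02), Barx1 (-0.32) and Gata4 (-0.18) did not pass over all genes. Nor did Pbx3 (1.77) and Foxf1 (-0.02), whose other probe sets differed by -0.059 and 1.77.

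Stromal genes of the white pulp rose for 10 of 16 measured members (11 when adjusted over the list alone; median 3.02 above all genes; camera adjusted p = 2.5e-12; adjusted p = 0.074 with an estimated correlation). The chemokine Cxcl13 attracts B cells, and Ccl19 (5.55 ± 0.24) attracts T cells and dendritic cells. Clu (5.82 ± 0.32) and Enpp2, which makes lysophosphatidic acid (5.26 ± 0.26), rose as well. Pdpn (1.26), Icam1 (0.75) and Tnfsf11 (-0.23) did not pass.

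Contractile genes of mural and smooth muscle cells formed the list with the largest shift. Of 18 measured members 17 rose, and all 18 did when adjusted over the list alone, with a median 4.75 above that of all genes (camera adjusted p = 3.9e-23; adjusted p = 0.048 with an estimated correlation). After Acta2 and Myl9, the light chain of smooth muscle myosin (6.57 ± 0.31), came Rgs5, a pericyte marker (5.88 ± 0.70), and Pln, phospholamban (5.84 ± 0.23). Kcnj8, a potassium channel subunit of pericytes, differed by 2.23 ± 0.75 and did not pass (adjusted p = 0.13).

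Extracellular matrix genes rose for 18 of 30 measured members (24 when adjusted over the list alone), with a median 2.47 above all genes (camera adjusted p = 1.5e-20; adjusted p = 0.13 with an estimated correlation). The proteoglycans Dcn (6.06 ± 0.42) and Bgn (5.59 ± 0.39), fibronectin Fn1 (5.53 ± 0.30) and matrix Gla protein Mgp (5.50 ± 0.37) rose most. Col1a1 (1.87), Col3a1 (1.96) and Col15a1 (-0.01) did not pass over all genes. Complement and coagulation genes of stroma rose for 10 of 15 members (13 when adjusted over the list alone; median 3.27 above all genes; camera adjusted p = 6.7e-14; adjusted p = 0.048 with an estimated correlation), and C3 (5.65 ± 0.38) and C4b (5.55 ± 0.26) joined Serping1 and C1s. Probes for C4b and C1s can also bind transcripts of their near-identical neighbours, so these values are uncertain as to the copy. Integrins and adhesion molecules of stroma rose for 9 of 15 members (13 when adjusted over the list alone; median 2.42 above all genes; camera adjusted p = 5.9e-11; adjusted p = 0.048 with an estimated correlation). The count was 5 without sorted array 2. Itga8 (5.18 ± 0.35) and Itga1 (5.005 ± 0.36), alpha subunits that pair with integrin beta 1, rose with Mcam (3.58 ± 0.38) and the mesenchymal cadherin Cdh11 (3.52 ± 0.35).

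Genes of BMP and TGF-beta signalling rose for 15 of 26 measured members, over all genes and adjusted over the list alone (median 2.09 above all genes; camera adjusted p = 8.6e-10; adjusted p = 0.048 with an estimated correlation). The receptors Bmpr1a (5.02 ± 0.24) and Bmpr2 (3.78 ± 0.26) and the latent TGF-beta binding proteins Ltbp4 (4.26 ± 0.38) and Ltbp1 (3.65 ± 0.32) rose most, while Tgfb1 (-1.22), Nog (-0.51) and Chrd (-0.58) did not pass. The count was 8 without whole spleen array 1 and 7 without sorted array 2, and 1 member fell without either whole spleen array. Genes of Wnt and Notch signalling rose for 10 of 23 members (13 when adjusted over the list alone; median 1.59 above all genes; camera adjusted p = 2.8e-08; adjusted p = 0.048 with an estimated correlation). The secreted Wnt antagonist Sfrp1 (4.98 ± 0.37), the ligand Jag1, the receptor Fzd1 (4.19 ± 0.50) and Notch3, the Notch receptor of mural cells (3.46 ± 0.36), led this list. Axin2 (-0.02), a transcriptional target of Wnt signalling, did not pass.

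Genes of bone, fat and cartilage lineages did not rise as lists. Of 14 osteogenic genes only Dmp1, a matrix protein of osteocytes, passed (3.05 ± 0.43), over all genes and adjusted over the list alone, and it did not pass without whole spleen array 1 (adjusted p = 0.051). Runx2 (-0.85), Sp7 (-0.31) and Alpl (-0.23) did not pass (list camera adjusted p = 0.26). None of the 14 passed without whole spleen array 1, 2 rose without sorted array 1 and 2 fell without whole spleen array 2. Of 12 adipogenic genes 4 rose, over all genes and adjusted over the list alone: the fatty acid transporter Cd36 (4.21 ± 0.87), Lpl, Apoe (2.30 ± 0.40) and Plin4 (1.43 ± 0.26). The uncorrected median of that list was -0.29 and its mean 0.75, in opposite directions, and camera gave an adjusted p of 0.22 with a positive direction. Adipoq (-0.31) and Pparg (-0.63) did not pass. With 1 array left out, the difference of Cd36 ran from 2.70 to 5.71. Cd36 lost its call without whole spleen array 1 or any 1 sorted array (adjusted p 0.053 to 0.119), Apoe without whole spleen array 1, sorted array 2 or sorted array 3 (0.059 to 0.086) and Plin4 without any 1 sorted array (0.076 to 0.103). The number of adipogenic genes that rose was 2 without whole spleen array 1 or sorted array 1 and 1 without sorted array 2 or 3, and 2 fell without whole spleen array 2. Of 10 chondrogenic genes none passed over all genes or over the list alone (1 higher at an unadjusted limma p under 0.05; camera adjusted p = 0.65), except for 1 that fell without whole spleen array 2; Sox9 differed by 0.09.

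**Figure D2:**
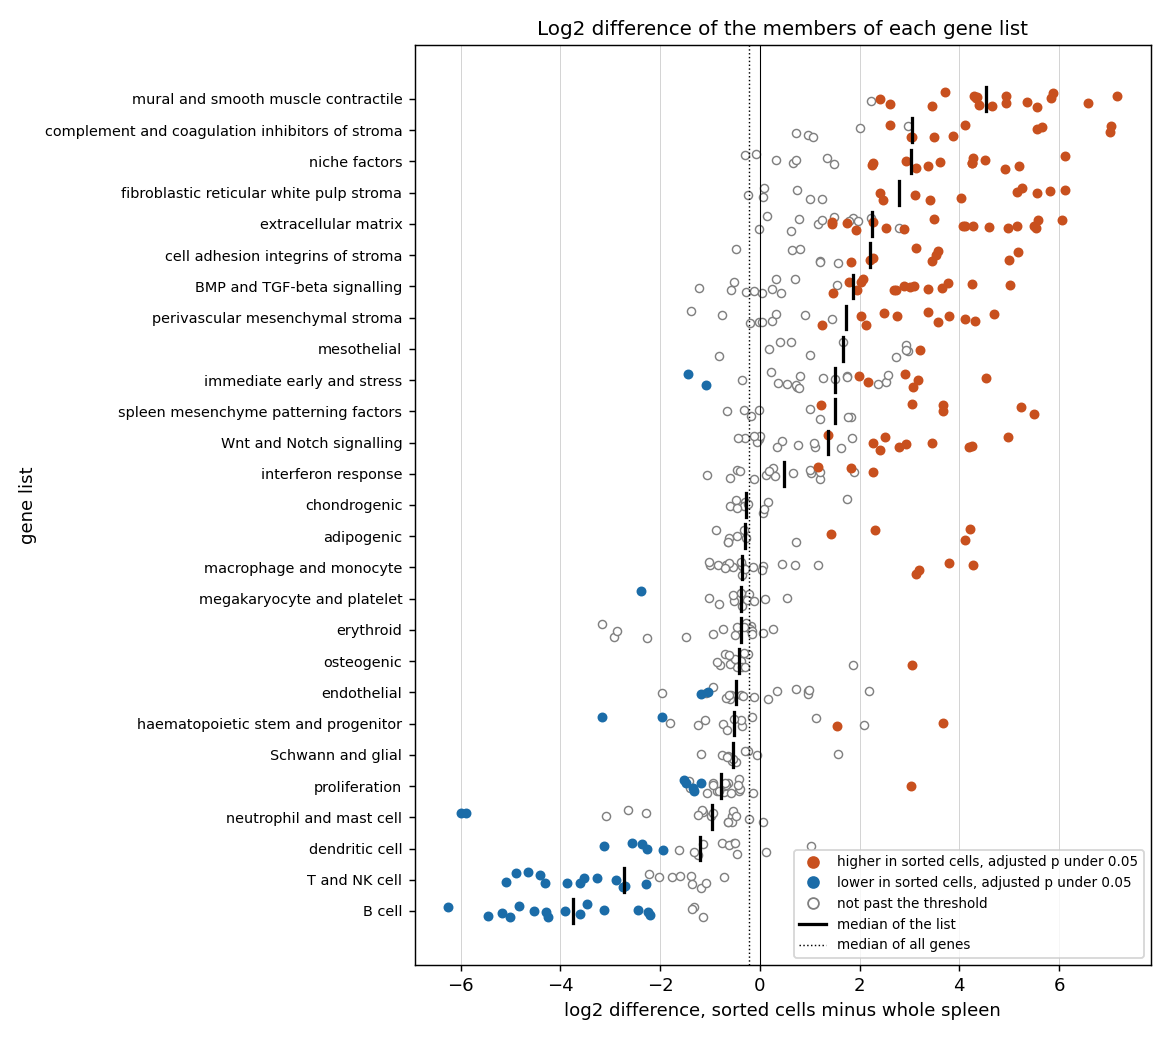
Log2 difference, sorted cells minus whole spleen (horizontal axis), of each measured member of the 27 tested gene lists (vertical axis, ordered by median); filled points passed an adjusted p of 0.05, orange where higher and blue where lower in sorted cells, open points did not pass, thick bars are list medians and the dotted line is the median of all genes, -0.22. All but 1 of the 18 mural and smooth muscle genes are filled and orange, and 15 of the 18 B cell genes are filled and blue.

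Markers of B cells fell for 15 of 18 measured members (17 when adjusted over the list alone), and the list's median lay at -3.53 relative to all genes (camera adjusted p = 2.6e-15; adjusted p = 0.048 with an estimated correlation). Ms4a1, Cd79b of the B cell receptor complex (-5.45 ± 0.32), the IgE receptor Fcer2a (-5.16 ± 0.31) and the adaptor Bank1 (-4.999 ± 0.24) fell most, and Ebf1 (-1.13, and 0.38 at its other probe set) did not pass. Markers of T and NK cells fell for 13 of 22 members (19 when adjusted over the list alone; median -2.49 relative to all genes; camera adjusted p = 3.2e-10; adjusted p = 0.13 with an estimated correlation). The interleukin 7 receptor Il7r (-5.08 ± 0.40), the NK receptor chain Klrd1 (-4.89 ± 0.47), Cd3d of the T cell receptor complex (-4.66 ± 0.75) and Cd8b1 (-4.40 ± 0.36) fell most. Cd3d lost its call without whole spleen array 1 (adjusted p = 0.085), and the count was 8 without sorted array 1 and 7 without sorted array 2. The T and NK median was -1.65 without whole spleen array 2.

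Dendritic cell genes fell for 5 of 16 members (7 when adjusted over the list alone; median -0.97 relative to all genes; camera adjusted p = 0.00098; adjusted p = 0.16 with an estimated correlation). These were the chemokine receptor Ccr7 (-3.12 ± 0.60), the class II genes H2-Aa (-2.56 ± 0.56) and H2-Eb1 (-2.27 ± 0.40), the invariant chain Cd74 (-2.35 ± 0.49) and H2-Ab1 (-1.95 ± 0.37), the last named after its value was seen. Class II genes resemble one another, and B cells express them too. The count was 2 without whole spleen array 1, 1 without sorted array 1, 0 without sorted array 3 and 2 after further quantile normalization, and the list's adjusted p was 0.0503 without whole spleen array 2. All 5 genes lost their calls without some array: Ccr7 without any 1 sorted array (adjusted p 0.076 to 0.091), H2-Aa (0.077 to 0.129) and Cd74 (0.055 to 0.106) without either whole spleen array or sorted array 1 or 3. H2-Eb1 lost it without whole spleen array 1 or sorted array 3 (0.070 to 0.088) and H2-Ab1 without whole spleen array 1 or sorted array 1 or 3 (0.062 to 0.094). Of 18 neutrophil and mast cell genes S100a8 and S100a9 alone fell, over all genes and adjusted over the list alone (median -0.74 relative to all genes; camera adjusted p = 0.00098; adjusted p = 0.29 with an estimated correlation), and 10 fell without whole spleen array 2. The median was -0.33 without whole spleen array 1. Camp (-3.09), Retnlg (-2.64) and Mpo (-1.13) did not pass.

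The macrophage and monocyte list did not move as a whole, with an uncorrected median of -0.36 and a mean of 0.38, in opposite directions (camera adjusted p = 0.38, positive direction). Its 4 called members, over all genes and adjusted over the list alone, rose: Mertk (4.27 ± 0.47) and Axl (3.79 ± 0.35), receptor tyrosine kinases that bind Gas6, the iron exporter Slc40a1 (3.19 ± 0.43), and Vcam1, which lost its call without whole spleen array 1 or any 1 sorted array (adjusted p 0.062 to 0.130). Csf1r (0.05), Cd68 (0.07), Lyz2 (-0.13) and C1qa (-0.65) did not pass, and 1 member fell without whole spleen array 2. On sorted array 2 the called Mertk (-0.03), Axl (-0.08) and Slc40a1 (0.15) differed little from the mean of sorted arrays 1 and 3, and Vcam1 by 0.51. The levels of C1qa (7.82), C1qc (8.52) and Lyz2 (9.75) on sorted array 2, by contrast, exceeded those on sorted arrays 1 (5.08, 5.26 and 6.23) and 3 (5.75, 6.43 and 8.91).

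Mesothelial genes, which mark the outer lining of abdominal organs, behaved in the same uneven way. Of 11 measured genes 1 passed, Gpm6a (3.20 ± 0.64), while 5 rose and Krt8 (-0.83) fell when adjusted over the list alone. The list's median lay 1.89 above all genes (camera adjusted p = 0.0024; adjusted p = 0.50 with an estimated correlation), with an adjusted p of 0.070 without whole spleen array 2 and a median of 1.20 without sorted array 2. Msln differed by 2.98 ± 0.95 and Upk3b by 2.92 ± 0.79 without passing, and both were highest on sorted array 2 (9.82 and 9.98, against 7.54 and 7.72 on sorted array 1 and 6.45 and 7.25 on sorted array 3). Gpm6a lost its call without either whole spleen array or sorted array 1 (adjusted p 0.058 to 0.117). It also lost it after further quantile normalization (0.051), where Krt8 alone passed, as lower. Of the 11 members 2 rose without sorted array 2 and without sorted array 3.

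**Figure D3:**
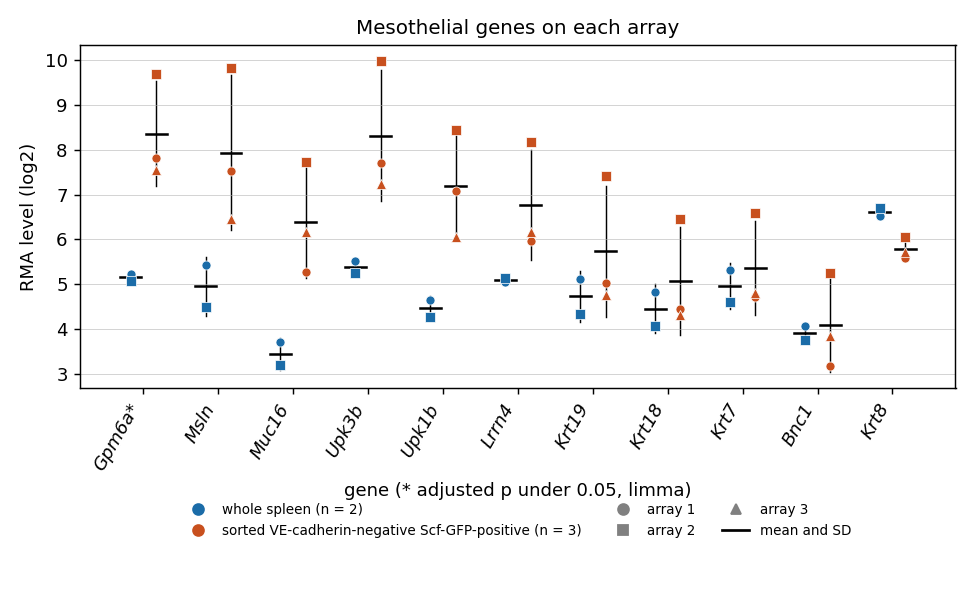
RMA levels (log2, vertical axis) of the 11 measured mesothelial genes on each array; points are arrays (circle 1, square 2, triangle 3), horizontal bars group means and vertical bars SDs, with whole spleen (n = 2) in blue and sorted cells (n = 3) in orange. Sorted array 2 is the highest of the sorted arrays for all 11 genes, with Msln at 9.82 against 7.54 and 6.45.

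Endothelial genes, the target of the exclusion gate, were not shifted as a list (20 measured, camera adjusted p = 0.42). At an unadjusted limma p under 0.05, 4 were higher and 9 lower. The list's median level in whole spleen was 5.03, near the medians of the whole spleen arrays (5.12 and 5.02), so a fall had limited room. Stab2, a scavenger receptor of sinusoidal endothelium (-1.18 ± 0.24), and Sox18 (-1.03 ± 0.23) fell, over all genes and adjusted over the list alone. Stab2 lost its call without any 1 sorted array (adjusted p 0.085 to 0.154) and Sox18 without those or whole spleen array 1 (0.084 to 0.160). As a result none fell without any 1 sorted array, 1 rose without sorted array 3 and 5 fell without whole spleen array 2. Pecam1 (-1.95), Plvap (0.98) and Esam (2.19) did not pass. Of 11 Schwann and glial genes none passed over all genes or over the list alone (1 higher and 5 lower at an unadjusted limma p under 0.05; camera adjusted p = 0.10); 3 fell without whole spleen array 2 and 1 rose without sorted array 1.

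Of 18 erythroid genes none passed, over all genes or over the list alone (4 lower at an unadjusted limma p under 0.05; camera adjusted p = 0.081, and 0.027 to 0.044 without whole spleen array 2, sorted array 1 or sorted array 2). Haemoglobin probe sets were lower by values that did not pass: Hbb-b1 (-3.15, adjusted p = 0.10), Hba-a1 (-2.92, 0.085) and Hba-a2 (-2.85, 0.094), whose copies the probes cannot tell apart. Without whole spleen array 2, 3 erythroid genes fell, and 1 fell without sorted array 3. Of 12 megakaryocyte and platelet genes Ppbp, a platelet chemokine, fell (-2.37 ± 0.43; 3 fell when adjusted over the list alone; camera adjusted p = 0.10). Ppbp lost its call without whole spleen array 1 or any 1 sorted array (adjusted p 0.051 to 0.081), leaving none of the 12, while 4 fell without whole spleen array 2 and 2 after further quantile normalization.

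Of 15 genes of haematopoietic stem and progenitor cells 2 rose and 2 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.32). Meis1 (3.68 ± 0.45), also in the patterning list, and Hlf (1.54 ± 0.32) rose, while Cd48 (-3.16 ± 0.28) and Myb (-1.96 ± 0.27) fell, and Kit (-0.66), the receptor of stem cell factor, did not pass. Hlf lost its call without any 1 of the 5 arrays (adjusted p 0.051 to 0.113), leaving 1 gene that rose, and Myb with array weights (0.056).

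Proliferation genes were lower: 5 of 24 fell and 1 rose (13 and 1 when adjusted over the list alone; median -0.55 relative to all genes; camera adjusted p = 6.7e-05; adjusted p = 0.13 with an estimated correlation). Ccna2 (-1.52 ± 0.24), Mki67 (-1.47 ± 0.34), Nusap1 (-1.35 ± 0.31), Tyms (-1.32 ± 0.27) and, named after its value was seen, Plk1 (-1.17) fell. The median was -0.97 without whole spleen array 1. None of the 24 genes passed without any 1 sorted array (Ccna2 adjusted p 0.059 to 0.083), and Mki67 (0.075), Nusap1 (0.080), Tyms (0.075) and Plk1 also lost their calls without whole spleen array 1, as Nusap1 did without whole spleen array 2 (0.064). Top2a, a topoisomerase of dividing cells, went the other way by 3.04 ± 0.62 (limma adjusted p 0.090 to 0.106 without any 1 sorted array). With 1 array left out, the difference of Top2a ran from 1.98 to 4.11. However, its 5 probe sets ran from -1.41 to 3.04 and 2 of them were lower in sorted cells.

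Immediate early and stress genes were higher: 6 of 23 rose and 2 fell (10 and 2 when adjusted over the list alone; median 1.73 above all genes; camera adjusted p = 5.5e-07; adjusted p = 0.21 with an estimated correlation). The small heat shock protein Hspb1 rose by 4.53 ± 0.43, although 1 of its 3 probe sets differed by -0.32, and Fosb (3.18 ± 0.53), Nr4a1 (3.08 ± 0.38) and Fos (2.91 ± 0.37), transcription factors induced within minutes by many stimuli, rose too. Myc (-1.44 ± 0.24) and Egr3 (-1.08 ± 0.24) fell, but not without any 1 sorted array (adjusted p 0.061 to 0.088 and 0.111 to 0.185). Fosb lost its call without whole spleen array 1 or sorted array 2 (0.070 to 0.077). Interferon response genes rose for 3 of 18 members (4 when adjusted over the list alone; median 0.71 above all genes; camera adjusted p = 0.0057; adjusted p = 0.33 with an estimated correlation): Oasl2 (2.27 ± 0.26), Ifit1 (1.83 ± 0.40) and Ifi44 (1.16 ± 0.24). That list did not pass after further quantile normalization (adjusted p = 0.055, median 0.38) or without whole spleen array 2 (0.13), where 1 member fell, and 1 gene rose without sorted array 2. Ifit1 lost its call without either whole spleen array or sorted array 1 or 2 (0.065 to 0.138), and Ifi44 without whole spleen array 1 or any 1 sorted array (0.054 to 0.161).

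Across the 27 lists, camera at its preset correlation called 18, and 7 with an estimated correlation: niche factors, mural and smooth muscle genes, complement and coagulation inhibitors, BMP and TGF-beta signalling, Wnt and Notch signalling, B cell markers and stromal integrins. The estimated correlations of the BMP and TGF-beta, Wnt and Notch and integrin lists were below the preset 0.01, yet their p rose too. Larger p with an estimated correlation are therefore not due to correlation alone.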

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

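All tests of explanations in this part were chosen after the results they bear on had been seen.

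Probe sets without a single gene symbol lay outside the gene comparison, and some of them carried a signal well above whole spleen. Of 4522 such probe sets, 73 were higher and 120 lower in sorted cells (limma, adjusted over all 28940 probe sets). That is 4.27% of them, while 1890 of 21310 named genes passed when adjusted over those genes. The largest rise was 7.92 ± 0.24 log2 units (SE; adjusted p = 0.00039), at probe set 10358652, which stood at 10.5, 10.3 and 10.8 on the sorted arrays and at 2.55 and 2.70 on the whole spleen arrays. Probe set 10358670 followed with 7.03 ± 0.28. The deposited table gives neither a gene name, and 54 of the 73 have no description at all. The number of probe set 10358654, used for Hmcn1 (6.41 log2 units higher), lies between 10358652 and 10358670. Which gene these read was not tested.

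The labels place the sorted cells both in bone marrow and in a study of the spleen, and spleen patterning factors rose in them. Ebf3, Adipoq, Foxc1, Alpl, Spp1 and Runx2, used by bone marrow stroma, had a mean difference from whole spleen of -0.073 log2 units (95% limits -0.80 to 0.65), but other genes of Scf-expressing marrow stroma rose, among them Cxcl12 (5.19), Pdgfra (4.32), Angpt1 (3.62) and Lepr (3.36). Tlx1, Tcf21, Nkx2-5 and Nkx2-3 had a mean difference of 2.68 (95% limits 1.64 to 3.73), while Barx1 (-0.32), Gata4 (-0.18) and Nkx3-2 (1.02) of the same list did not pass. White pulp stroma genes, which a source in spleen would bring, rose for 10 of 16 members, among them Cxcl13 (6.11, to a mean level of 11.76), Ccl19 (5.55), Ccl21a (5.17) and Madcam1 (3.40). The genes of both means, and Ccl21a and Madcam1, were picked after their values had been seen. The white pulp and patterning lists as wholes were fixed beforehand, and their rises go with a source in spleen. No bone marrow sample shows how far marrow stroma carries these genes, so a source in bone marrow is not excluded here.

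Mesothelial genes stood highest on sorted array 2 among the sorted arrays, for 11 of 11 genes, with a median 2.02 log2 units above the mean of the other sorted arrays (percentile 100 of 10000 random lists of matched level). The median of all genes was 0.037 higher there, but RMA holds array medians close together, so this cannot decide on scaling of that array. Its interquartile range, 2.95, lay between those of sorted arrays 1 (2.87) and 3 (3.04). Mesothelial cells or their RNA in that sample may be the source, which stays open, since the values at hand (Upk3b 9.98, Msln 9.82 and Gpm6a 9.70 there; 0 of 11 genes in another list, 2 above the gene median in whole spleen) are those in which the pattern was seen. Macrophage and monocyte genes were also higher there (percentile 100, 14 of 23 genes highest on that array, median 0.52, Lyz2 9.75), with 14 of the 23 above the gene median in whole spleen and 1 in another list, and whether macrophages came along is open for the same reason. The gate on GFP and VE-cadherin was meant to remove cells without Scf expression, but how pure the sorted cells were is not known here. No biological explanation was tested, since the design has no groups within the sorted cells.

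The whole spleen arrays differed more from each other than the sorted arrays did. After quantile normalization their correlation was 0.889, against 0.967 for the lowest sorted pair. A linear change of scale leaves a Pearson correlation as it was. These values therefore cannot decide whether scale widened the SD per gene, nor do they bear on separate RMA runs. Another cell make-up of the 2 samples may be the reason: array 1 minus array 2 gave a median of -1.06 log2 units for T and NK cell genes (5 of 22 higher on array 1; percentile 0.02 of random lists of matched level), 0.91 for neutrophil and mast cell genes (14 of 18; 99.99), 0.36 for erythroid genes (16 of 18; 88.2) and -0.23 for B cell genes (7 of 18; 10.7), where 61.6% of all genes were higher on array 1. The first 2 of these shifts go with such a difference but were seen before they were tested, and the spread within the lists (percentiles 9.04 to 99.98) decides nothing, since abundant markers of a cell type shift further than dim ones. No biological explanation was tested, as both arrays belong to the same group.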

How the results depend on the processing

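The counts and medians of list members and gene families without each array or after further quantile normalization were chosen after the results were seen; the other alternatives were planned. No called gene among the 1890 changed sign under any of the 13 settings of the gene test, and no called list reversed. Array weights left 910 genes past the threshold, 681 higher and 229 lower, all at least 2-fold (the whole spleen arrays had a weight of 0.386 each; the cause of the drop was not tested); treat, which tests against a 2-fold change, left 670 (526 higher, 144 lower). Leaving out 1 array gave 943 (sorted array 2) to 7115 (whole spleen array 2) genes, 687 to 3137 higher and 256 to 3978 lower, and at 2-fold 943 to 5459, 687 to 2897 and 256 to 2562; with 1 whole spleen array left, it is assumed to vary like the sorted arrays. Kitl ranged from 4.32 to 4.71 and Cdh5 from -1.21 (whole spleen array 1 left out, the only setting in which it passed) to -0.65 (whole spleen array 2 left out); the cause was not tested. Gene lists past the threshold numbered 18 to 19 without 1 sorted array and 7 with an estimated correlation. Correlation within lists does not account for all of the larger p. BMP and TGF-beta genes had an estimated correlation of -0.0025, below the preset 0.01, yet their unadjusted camera p went from 2.9e-10 to 0.0059. Stromal integrins (-0.0028, 1.5e-11 to 0.0055) and Wnt and Notch genes (-0.013, 1.2e-08 to 0.0081) behaved alike. The remaining cause was not tested. The correlation within groups fell from a mean of 0.971 to 0.952 (sorted) and from 0.887 to 0.825 (whole spleen) without the dimmest genes, and to 0.863 (whole spleen) with the mean of probe sets; the cause was not tested. The count was 1866 after further quantile normalization, 1852 after median centring, 1945 without dim genes, 1933 with the mean of probe sets and 1843 with trend and robust settings.

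With the replicate number as a block, 1619 genes passed, 1377 of them among the 1890, and no list call changed. Number 3 occurs only among the sorted arrays, so sorted array 3 had no influence on the differences in this fit. Those of Kitl (4.71) and Cdh5 (-0.93) were the same as without that array. The block fit is therefore no check on all 5 arrays. Of the 177 called genes of the lists 19 did not pass with the block, and 19 others did; those named in the text that did not were Ccna2, Egr3, Hlf, Ifi44, Mki67, Myc, Nkx2-3, Nusap1, Plin4, Plk1, Sox18, Stab2 and Tyms (adjusted p 0.061 to 0.228). Samples of the same number did not deviate together (correlations 0.051 and -0.065), and the labels do not say that the numbers pair samples. The deviations of the 2 whole spleen arrays are mirror images of each other, so these correlations are a weak check on pairing.

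Of 177 called list genes, 15 lost the call after further quantile normalization, 67 with array weights and 14 to 56 without 1 array; among 285 uncalled ones, 1 to 47 gained a call without 1 array, and 9 to 33 changed sign. Of the 27 lists, fry ended the calls of mesothelial genes (0.24) and the interferon response (0.098) and called Schwann and glial (0.031) and haematopoietic stem and progenitor genes (0.0084). Removal of dim genes brought in erythroid (0.028) and megakaryocyte genes (0.045). The series matrix moved nothing. Arrays compress differences of genes near background, and noise there can move a fitted difference either way.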

Other observations

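The gene families in this part, and their counts without 1 array, were chosen after the data were seen, and family medians are not corrected for the median of all genes (-0.22). Grouping genes by the stem of their symbol gave 322 families of 8 to 80 members, of which 7 were higher and 12 lower by camera at its preset correlation, and 0 with an estimated correlation (for histones an unadjusted p of 0.053 and an adjusted p of 0.84). Replication-dependent histone genes formed the family with the smallest p: 27 of 60 fell and none rose, with a median of -1.47 log2 units (camera adjusted p = 3.8e-11) and -1.43 after further quantile normalization. Hist1h3b (-2.44 ± 0.36) and Hist1h3d (-2.42 ± 0.37) were among them, named after their values were seen; probes for these near-identical genes cannot be told apart. Family medians per array were 8.90 and 8.47 in whole spleen and 6.72, 7.41 and 6.78 in sorted cells, and 19 to 38 members fell without 1 array (38 without whole spleen array 2).

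Gimap genes, GTPases of lymphocytes, fell for 6 of 8 members with a median of -3.67 (camera adjusted p = 1.6e-05), and 6 or 7 fell without any 1 array; Gimap4 fell by 4.28 and Gimap7 by 5.08. The 52 ribosomal protein genes of the large subunit had a median of -0.82, and of -0.40 after further quantile normalization, so the size of that difference moved with the scaling. Genes of intraflagellar transport, which builds cilia, rose for 4 of 12 members: Ift81 (3.03 ± 0.24), Ift57 (2.07 ± 0.36), Ift46 (1.46 ± 0.30) and Ift172 (1.32 ± 0.24). That family's adjusted p was 0.020, with 0.078 after further quantile normalization and 0.080 without whole spleen array 1, and the number that rose was 2 without whole spleen array 1, 2 without sorted array 1, 1 without sorted array 2 and 1 without sorted array 3.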
